A study of Mus musculus with 24 samples.

How the data were processed

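RNA was sequenced from CD11b-positive cells of frontal cortex and striatum of male mouse offspring aged 8 to 10 weeks. Dams had either been given an immune stimulus in pregnancy (maternal immune activation, MIA) or served as controls, and each offspring received saline or lipopolysaccharide (LPS, 4500 EU/g, intraperitoneal) 18 h before collection. Per the labels, brains were perfused, meninges were removed, the tissue was dissociated with papain and cleared of debris, and CD11b-positive cells, a fraction rich in microglia, were taken with magnetic beads. Libraries came from oligo-dT primed cDNA of the Smart-Seq2 type.

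The deposited table held 1 expected count per gene and library for 24 libraries, and per the submitters' processing notes reads had been aligned with STAR and summed per gene with RSEM, and DESeq2 had been used. Versions of these tools and the genome build were not given in the sources used here, so no coordinates are printed. Of all values, 6.92% were not whole numbers (20.3% of the values above 0), and expected counts were rounded to whole numbers before any test. The table listed 55487 Ensembl gene identifiers. Of these, 55141 matched a gene symbol, and the other 346 kept their identifier. RSEM shares reads among near-identical genes, so the values of such genes (Bcl2a1a and Bcl2a1d, Ifi204 and Ifi207, Phf11b and Phf11d, the Oas, H2, Hba and Hbb genes) depend on that split.

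Groups were set from the labels: control or MIA, cortex or striatum, saline or LPS, with 3 libraries in each of the 8 groups. The title of MIA striatum LPS replicate 3 marks it as excluded by the submitters. It was left out of the fit, which leaves 23 libraries and 2 in that group, and it was added back as an alternative. The labels do not say whether same-numbered libraries, or replicates of a group, come from separate animals, so the p-values measure the spread between these samples. The immune stimulus was given to dams and the litter of each offspring is not given. Differences between MIA and control therefore cannot be told apart from differences between litters. In the 23 libraries, total counts ran from 19453300 to 29480500, and 17723 to 20324 genes had a count in a library.

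Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 8 groups (minimum count 10, minimum total count 15), which left 17139 genes. Libraries were scaled with TMM, and a quasi-likelihood negative binomial model with 1 term per group was fitted to all 23 libraries (15 residual degrees of freedom). From this 1 fit came 14 comparisons: the LPS effect in each of 4 prenatal and regional groups, the MIA effect in each of 4 regional and treatment groups, the MIA by LPS interaction in each region, the striatum minus cortex difference in saline for control and for MIA, and the LPS by region interaction for control and for MIA. Two-sided p-values were adjusted within each comparison by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Fold changes are log2 with the standard error (SE) implied by the quasi-likelihood F statistic. Levels are counts scaled to a common library total (CPM) as mean ± SD, and scores per library use log2 CPM with a prior count of 2.

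Gene lists were fixed from textbook knowledge, 31 lists with 726 genes, of which 713 were tested. They cover microglial states, innate and interferon responses, antigen presentation, metabolism, stress, and markers of the other cells a CD11b sort of brain can hold. For each list the called members were counted over all genes and adjusted over the list alone. Lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 31 lists of a comparison. camera was also run with an estimated correlation and fry was run beside it. Of 198 list calls with the preset correlation, 30 held with an estimated correlation, and the text gives that p beside the list results. The size of the LPS response was compared between MIA and control offspring over genes called for the LPS effect averaged over both prenatal groups with a change of at least 2-fold, as the mean difference in log2 fold change, signed so that a negative value is a smaller response in MIA. The same genes were tested with fry on the interaction, adjusted over 4 tests. fry tests the joint direction of standardised gene statistics and not the mean itself, so its p and the mean can differ. In the alternatives, a response size passed at an unadjusted fry p under 0.05.

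The named-gene rule had 4 parts. It took for each comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, passing over predicted names. It took up to 4 called members of each list with the smallest adjusted p. It took 10 genes of interest in every comparison (P2ry12, Tmem119, Cx3cr1, Il1b, Tnf, Ccl2, Cxcl10, Isg15, Tlr4 and Cd14), and the sex genes Xist, Ddx3y and Eif2s3y as a check. With 3 libraries against 3, groups of pure noise do not overlap in 10% of genes. Groups, comparisons, lists, the named-gene rule and the alternatives of the next paragraph, except where stated there, were chosen before the data were examined, and the alternatives and tests chosen later are named as such.

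Alternatives were RLE size factors, no filter on low counts, a term for the replicate number, a fit of only the compared groups, limma voom with quality weights, DESeq2 1.42.0, the excluded library added back, each library left out in turn, and other definitions of the response size. A score of other-cell markers as a covariate, and the whole fit without MIA cortex LPS replicate 3, were added after the data were seen. Same-numbered libraries could be paired by their residuals in the LPS effect in MIA cortex, where correlations between numbers ran from 0.124 to 0.315 and every library fitted best with its own number. A term for the number gave 2314 calls there against 2039. The same held between control cortex LPS and control striatum LPS (0.275 to 0.314) but not between the saline libraries of these regions (0.0422 to 0.168). No comparison set these LPS groups against each other alone. It also held between control cortex LPS and control striatum saline (0.0808 to 0.233). Those mice, like the LPS and saline mice of MIA cortex, were treated differently and cannot be the same animals. These fits were picked from all pairs of groups, so they alone do not show pairing by number. Residuals of the used libraries numbered 3, however, correlated positively between most groups, for instance at 0.300 between MIA cortex and striatum saline. The exceptions were MIA cortex LPS replicate 3 with control cortex LPS (-0.161), control striatum saline (-0.0717) and control striatum LPS (-0.00382). A shift shared by libraries numbered 3 thus stays open, and the reported fit has no term for it. Overlaps between regions are set beside the number expected from independent calls, which animals shared between regions would raise.

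The single-comparison test was tested on simulated data with 50 true genes at each fold. In the layout of the LPS effect in control cortex it found 12% of genes changed 1.5-fold, 36% changed 2-fold, 62% changed 4-fold and 90% changed 8-fold, with 7 false calls among 16670 genes. In the layout of the LPS effect in MIA striatum it found 4%, 26%, 66% and 82%, with 4 false calls among 16640 genes. Response-size differences simulated at -0.5 were estimated at -0.498 on average, and those simulated at 0 at 0.0165. The unadjusted fry p was under 0.05 in 10 of 10 and 1 of 10 of these runs. All simulations drew genes independently, without shifts shared by the genes of a library or RNA of other cells. Their accuracy therefore does not carry over to the real libraries.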

Results

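Bulk RNA-seq libraries were made from CD11b-sorted cells of 2 brain regions of adult male mice, with 3 libraries for each combination of prenatal history (control or MIA), region (frontal cortex or striatum) and treatment (saline or LPS). The comparisons asked what LPS did in each region, whether MIA offspring differed from controls at rest and after LPS, and how the regions differed. The 23 libraries used held 19453300 to 29480500 counts each. Microglial genes were among the most abundant. P2ry12 (ENSMUSG00000036353.13), the ADP receptor of surveying microglia, stood at 5530 ± 283 CPM (SD, n = 3) in control cortex saline, and Cx3cr1, the fractalkine receptor, at a mean of 8265 CPM. Xist, which is expressed from an inactive X chromosome, lay between 0 and 0.739 CPM in the libraries used, and the Y-linked genes Ddx3y and Eif2s3y lay at 48.5 to 96.0 and 38.8 to 65.0 CPM.

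Markers of other cells were also present, at levels that differed between groups and libraries. The endothelial and pericyte list scored 6.19, 5.97 and 5.20 mean log2 CPM in the 3 control striatum saline libraries and 4.61, 4.01 and 4.33 in the 3 control cortex saline libraries. MIA cortex LPS replicate 3 stood apart from the other libraries of its group, with a neuron score of 4.24 against 1.02 and 0.47 and an interferon score of 6.22 against 4.25 and 4.19. MIA cortex saline replicate 1 had a neutrophil score of 3.67 against 1.96 and 2.08 in replicates 2 and 3. Mitochondrial genes took 1.93% to 4.37% of counts in the libraries used.

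**Figure D1:**
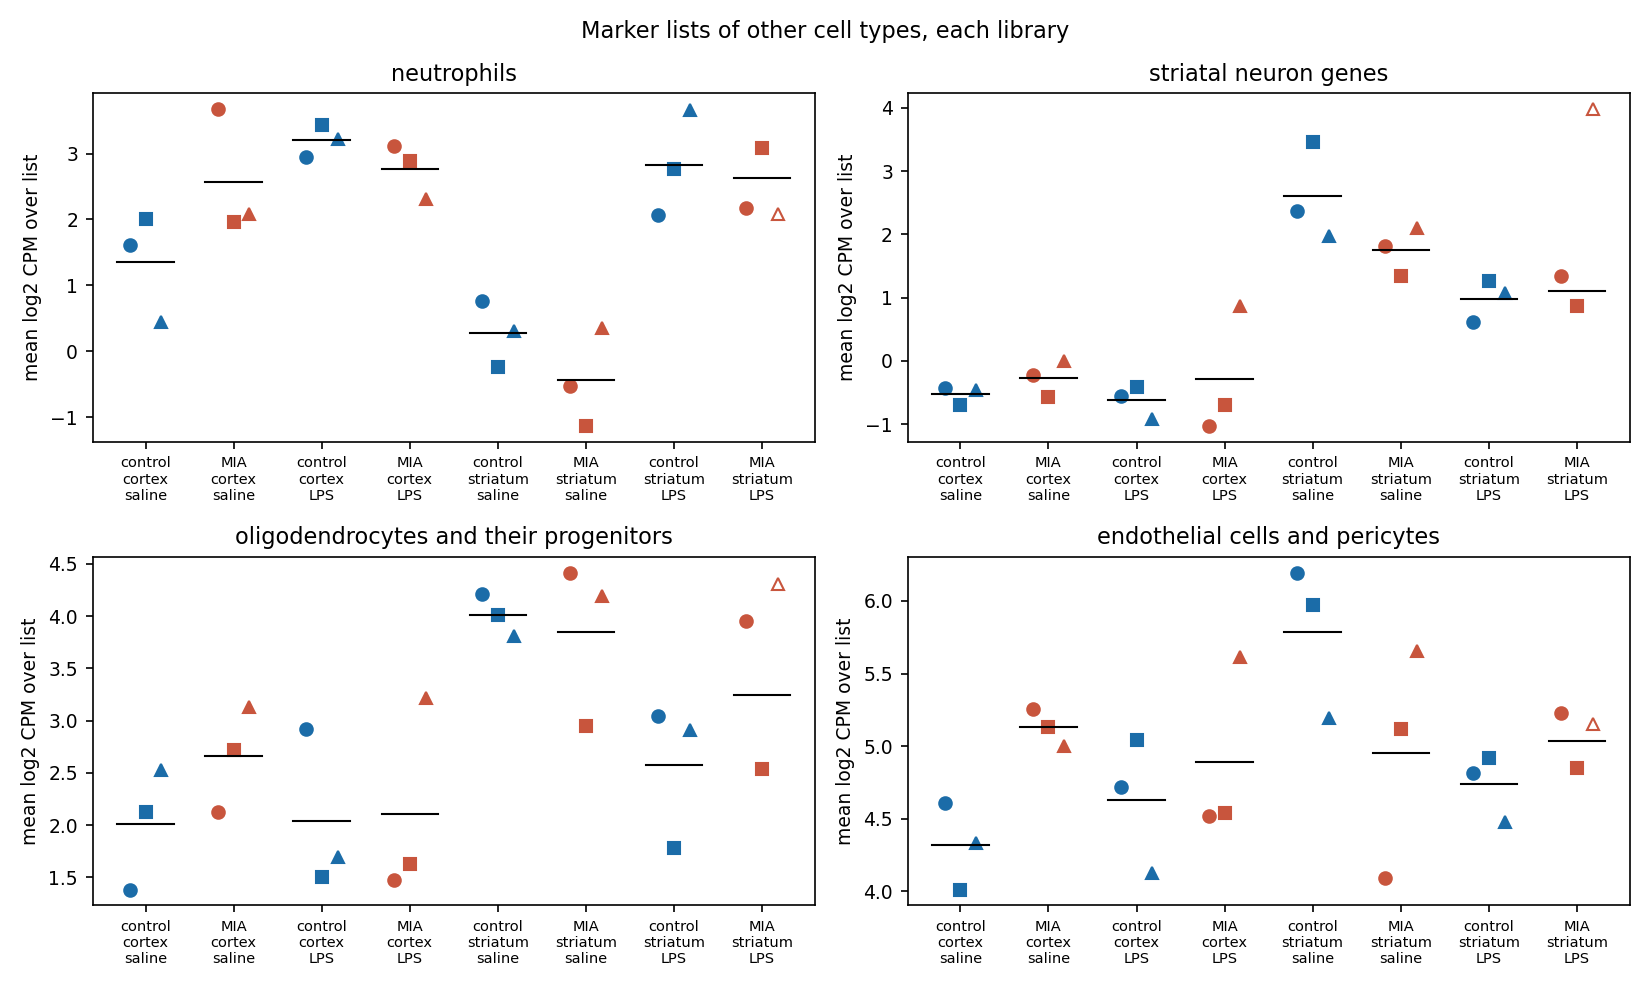
Mean log2 CPM over the neutrophil, striatal neuron, oligodendrocyte and endothelial marker lists (vertical axes) for each library by group, with control in blue, MIA in red, circles, squares and triangles for replicates 1, 2 and 3, a hollow triangle for the excluded library and black bars for the mean of the libraries used. Neutrophil scores in MIA cortex saline reach 3.67, and endothelial scores are highest in control striatum saline at 6.19.

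LPS in control cortex lowered genes of resting microglia and raised genes of innate inflammation. P2ry12 fell from 5530 ± 283 to 1134 ± 255 CPM (SD, n = 3 and 3), a log2 fold change of -2.29 ± 0.18 (SE, adjusted p = 3.2e-08). Il1b (ENSMUSG00000027398.13), which encodes the cytokine interleukin-1 beta, rose from 113 ± 5.63 to 1128 ± 486 CPM, a log2 fold change of 3.32 ± 0.24 (adjusted p = 1.5e-08). The chemokine gene Ccl12 (ENSMUSG00000035352.3) rose from 46.9 ± 3.35 to 1332 ± 136 CPM, by 4.83 ± 0.31 (adjusted p = 2.5e-09). The largest rise under the named-gene rule was that of the acute-phase gene Saa3, from a mean of 0.651 to 765 CPM (10.21 ± 1.44, adjusted p = 3.5e-05), and the largest fall that of Gkn3, from 10.8 to 0.633 CPM (-4.06 ± 0.77, adjusted p = 0.00066). In all, edgeR called 3114 genes, 1871 higher and 1243 lower, of which 947 and 640 changed at least 2-fold.

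Of the 27 measured homeostatic microglia genes in control cortex, 22 fell and 5 did not pass (24 fell adjusted over the list alone), with a list median of -0.85 (adjusted p = 0.0018 with an estimated correlation). Besides P2ry12 these included Gpr34 at -2.48 ± 0.12, Upk1b at -3.96 ± 0.24, and Siglech, a lectin gene typical of microglia, at -1.76 ± 0.16. Tmem119 (-0.76 ± 0.22, adjusted p = 0.017) and Cx3cr1 (-0.49 ± 0.14, adjusted p = 0.019) were called by a narrow margin. Tmem119 was not called without control cortex LPS replicate 1 (adjusted p = 0.0716), LPS replicate 2 (adjusted p = 0.083) or saline replicate 3 (adjusted p = 0.0901). Cx3cr1 was not called without LPS replicate 2 (adjusted p = 0.0703) or 3 (adjusted p = 0.0554) or saline replicate 2 (adjusted p = 0.0562) or 3 (adjusted p = 0.083).

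Of 28 cytokine and chemokine genes in control cortex, 24 rose and 4 did not pass (25 adjusted over the list alone), with a median of 2.26 (adjusted p = 0.0078 with an estimated correlation). Tnf rose by 2.85 ± 0.27, the interleukin-1 receptor antagonist gene Il1rn by 4.55 ± 0.41, the monocyte attractant gene Ccl2 by 2.16 ± 0.28 and Cxcl10 by 3.13 ± 0.38. Of 29 NF-kB feedback and target genes, 18 rose, 1 fell and 10 did not pass (22 and 1 adjusted over the list alone; adjusted p = 0.024 with an estimated correlation), among them Sod2, a mitochondrial antioxidant enzyme gene, at 1.70 ± 0.16 and Lcn2, which encodes an iron-siderophore binding protein, at 5.78 ± 0.68. Of the 22 genes for LPS sensing, 3 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.60 with an estimated correlation). The co-receptor gene Cd14 rose by 1.62 ± 0.24 and Tlr2 by 1.70 ± 0.16, while Tlr4, which encodes the LPS receptor, was at -0.16 ± 0.25 (adjusted p = 0.75). Among phagocytic and pattern receptors, 12 of 27 rose and 3 fell (13 and 6 adjusted over the list alone; adjusted p = 0.064 with an estimated correlation). The Fc receptor gene Fcgr4 rose from 17.6 ± 2.69 to 448 ± 77.1 CPM (4.67 ± 0.19, adjusted p = 5.7e-12), and the scavenger receptor gene Msr1 rose by 4.72 ± 0.30. The decoy receptor gene Il1r2 rose by 7.58 ± 0.61, within a list of 21 negative regulators of which 7 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). Without control cortex LPS replicate 3 the count of phagocytic receptors that fell was 5. The single fall among NF-kB genes was not called without LPS replicate 3 or saline replicate 2 or 3.

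All 40 measured interferon response genes rose in control cortex, with a median of 2.70 (adjusted p = 0.054 with an estimated correlation). Isg15 (ENSMUSG00000035692.7), a ubiquitin-like interferon-induced gene, rose from 2.23 ± 0.321 to 28.4 ± 7.12 CPM (3.67 ± 0.55, adjusted p = 6.5e-05), Ifitm3 by 4.14 ± 0.38 and Oasl2 by 4.11 ± 0.48. Of 22 genes of MHC class I antigen presentation, 16 rose and 6 did not pass (17 adjusted over the list alone), with a median of 1.00 (adjusted p = 0.064 with an estimated correlation), among them the proteasome activator gene Psme2 at 1.39 ± 0.15 and B2m at 1.00 ± 0.15. Of 37 oxidative phosphorylation genes, 25 rose and 12 did not pass (29 adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), including the cytochrome c gene Cycs at 1.15 ± 0.14. With LPS, 24 of these genes rose in control striatum, 5 in MIA cortex and 4 in MIA striatum. Markers of blood leukocytes also rose in control cortex. Of 19 monocyte genes 11 rose (13 adjusted over the list alone; adjusted p = 0.048 with an estimated correlation), Ms4a4c by 4.48 ± 0.39. Of 18 neutrophil genes 8 rose (9 up and 1 down adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), Lrg1 by 6.72 ± 0.52. Without control cortex saline replicate 3, 16 oxidative phosphorylation and 7 monocyte genes were called.

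**Figure D2:**
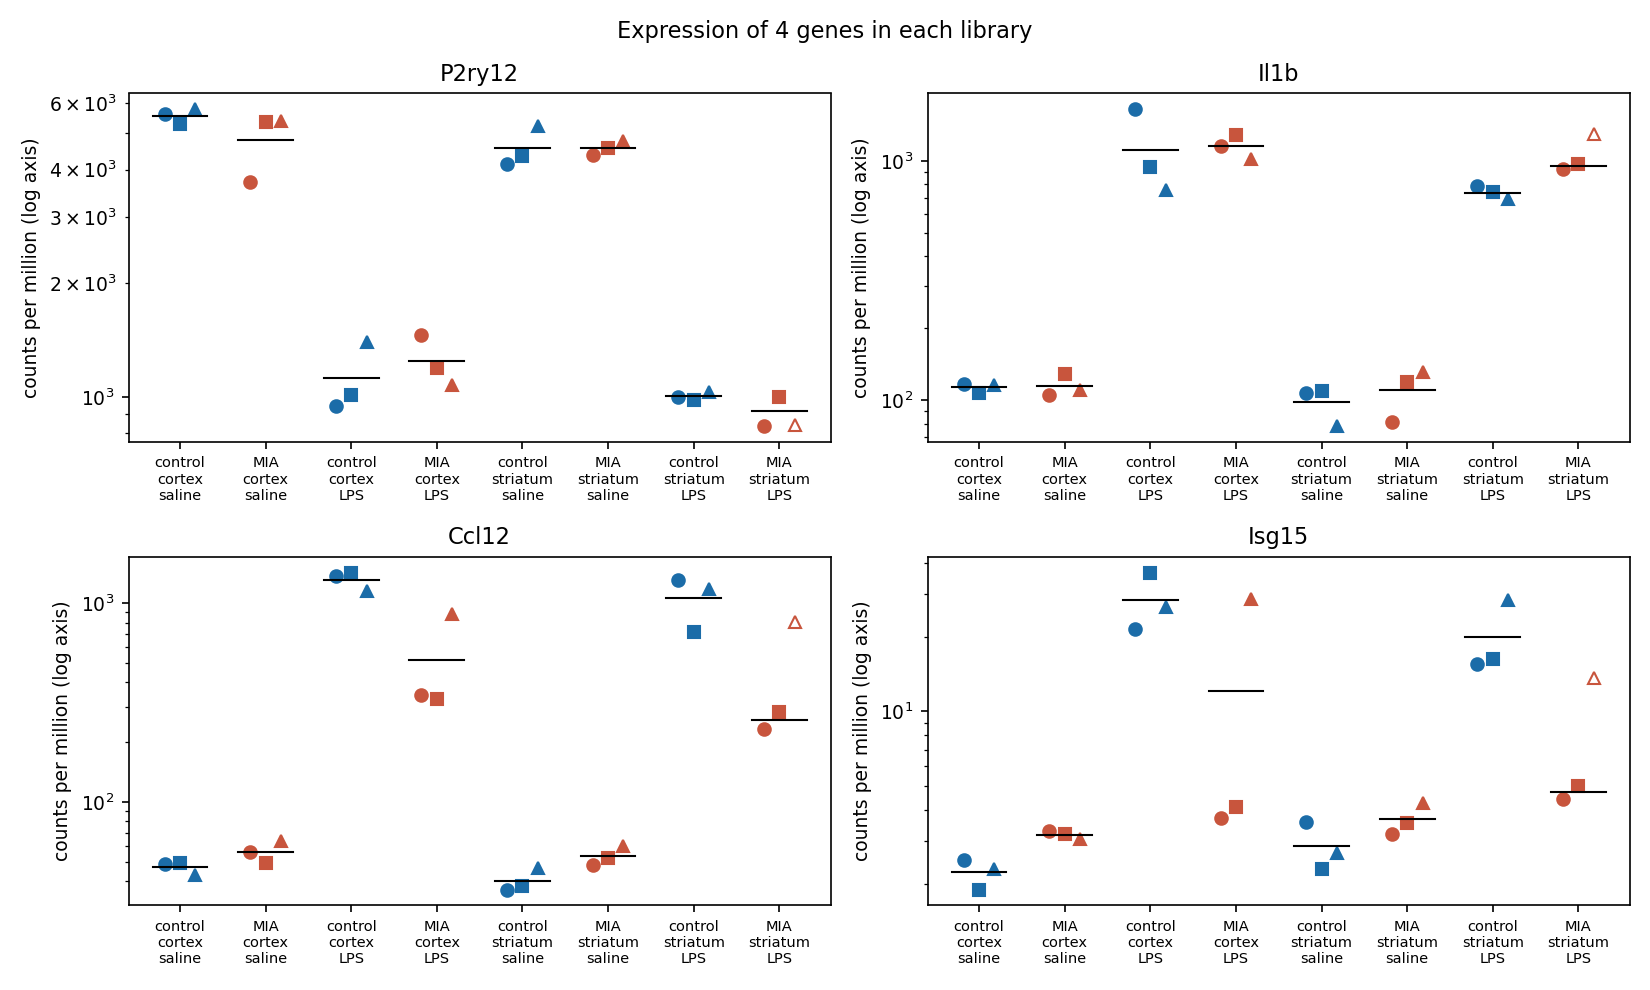
Level in CPM (log axis) of P2ry12, Il1b, Ccl12 and Isg15 in each library by group, with control in blue, MIA in red, circles, squares and triangles for replicates 1, 2 and 3, a hollow triangle for the excluded library and black bars for the mean of the libraries used. Group means of P2ry12 after LPS lie at 924 to 1225 CPM in all 4 groups, while those of Ccl12 lie at 1332 and 1074 CPM in control and 501 and 261 CPM in MIA cortex and striatum.

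In control striatum LPS also lowered genes of resting microglia and raised genes of innate inflammation. P2ry12 fell from 4607 ± 573 to 1008 ± 29.5 CPM (-2.19 ± 0.18, adjusted p = 4.5e-08, n = 3 and 3), and Il1b rose from 98.9 ± 17.7 to 742 ± 55.3 CPM (2.91 ± 0.24, adjusted p = 5.5e-08). Ccl12 rose from 40.6 ± 5.63 to 1074 ± 324 CPM (4.73 ± 0.31, adjusted p = 3.3e-09), and Fcgr4 rose to 425 ± 104 CPM (4.70 ± 0.19, adjusted p = 5.2e-12). Tnf rose by 2.54 ± 0.27, Ccl2 by 2.48 ± 0.28, Cxcl10 by 2.38 ± 0.37 and Cd14 by 1.79 ± 0.24. Tlr4 was at 0.17 ± 0.25 (adjusted p = 0.70) and Cx3cr1 at -0.30 ± 0.14 (adjusted p = 0.15). The call was 3576 genes, 2180 higher and 1396 lower, of which 989 and 864 changed at least 2-fold. With control cortex, 1555 genes rose in both regions against 238 expected from independent calls, and 813 fell in both against 101 expected.

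Homeostatic genes fell in 18 of 27 cases in control striatum (20 adjusted over the list alone), with a median of -0.67 (adjusted p = 0.0099 with an estimated correlation), and 23 of 28 cytokine genes rose (23 adjusted over the list alone; median 2.37, adjusted p = 0.0099 with an estimated correlation). Interferon genes rose in 36 of 40 cases (37 adjusted over the list alone; median 2.19, adjusted p = 0.068 with an estimated correlation), Isg15 from 2.87 ± 0.638 to 20.1 ± 7.04 CPM (2.81 ± 0.53). MHC class I genes rose in 17 of 22 cases (18 adjusted over the list alone; median 0.93, adjusted p = 0.088 with an estimated correlation). Of the phagocytic receptors 13 rose and 3 fell (14 and 3 adjusted over the list alone; adjusted p = 0.04 with an estimated correlation), with 1 fall left without control striatum LPS replicate 2. Of 24 disease-associated microglia genes 9 rose and 5 fell (11 and 5 adjusted over the list alone; adjusted p = 0.068 with an estimated correlation), and Cd63, a lysosomal membrane gene, rose by 2.31 ± 0.15. Tmem119 was at -0.62 ± 0.22 (adjusted p = 0.047) and was not called without LPS replicate 1 (adjusted p = 0.111), LPS replicate 2 (adjusted p = 0.204) or saline replicate 3 (adjusted p = 0.249).

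Markers of other cells moved with LPS in control striatum in both directions. Of 18 neutrophil genes 11 rose (12 adjusted over the list alone; median 3.17, adjusted p = 0.11 with an estimated correlation) and of 19 monocyte genes 13 rose (13 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation). Of 23 endothelial and pericyte genes 11 fell and 1 rose (15 and 1 adjusted over the list alone; median -1.19, adjusted p = 0.40 with an estimated correlation). Itm2a fell from 381 ± 180 to 36.1 ± 15.0 CPM (-3.40 ± 0.49, adjusted p = 4.3e-05) and the VEGF receptor gene Flt1 was at -2.18 ± 0.40 (adjusted p = 0.00055). Of 19 striatal neuron genes 6 fell (7 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), among them the enkephalin gene Penk at -2.60 ± 0.60, and of 20 oligodendrocyte genes 4 fell (4 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation). The endothelial count was 7 without LPS replicate 2 or 3 and 6 without saline replicate 1 or 2. The striatal neuron count was 3 without saline replicate 2, and the oligodendrocyte count was 1 without LPS replicate 2 or saline replicate 1 and 2 without LPS replicate 3.

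In MIA cortex LPS lowered homeostatic genes and raised cytokine genes and part of the interferon genes. P2ry12 fell from 4780 ± 925 to 1225 ± 229 CPM (-1.96 ± 0.18, adjusted p = 3.2e-07, n = 3 and 3), and Il1b rose from 114 ± 12.6 to 1134 ± 172 CPM (3.31 ± 0.24, adjusted p = 2.5e-08). Ccl12 rose from 56.1 ± 6.51 to 501 ± 279 CPM (3.16 ± 0.29, adjusted p = 3.6e-07), Fcgr4 from 16.0 ± 0.755 to 307 ± 31.4 CPM (4.27 ± 0.19), Tnf by 2.27 ± 0.27, Cxcl10 by 1.95 ± 0.37 and Cd14 by 1.43 ± 0.23. Tlr4 was at 0.14 ± 0.25 (adjusted p = 0.82). The call was 2039 genes, 1208 higher and 831 lower, of which 546 and 453 changed at least 2-fold. In both prenatal groups 1026 genes rose in cortex against 132 expected, and 646 fell against 60 expected.

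Of the homeostatic genes 19 of 27 fell in MIA cortex (23 adjusted over the list alone; median -0.72, adjusted p = 0.0025 with an estimated correlation), and 17 of 28 cytokine genes rose (23 up and 1 down adjusted over the list alone; median 1.49, adjusted p = 0.013 with an estimated correlation). Interferon genes rose in 23 of 40 cases (35 adjusted over the list alone; median 1.41, adjusted p = 0.24 with an estimated correlation), a count of 8 with a median of 0.43 without LPS replicate 3 and of 12 without saline replicate 1. Isg15 was at 11.5 ± 13 CPM after LPS against 3.16 ± 0.147 CPM in saline (1.87 ± 0.51, adjusted p = 0.019), and was not called without LPS replicate 3 (adjusted p = 0.561) or without saline replicate 1, 2 or 3 (adjusted p = 0.0601, 0.0597 and 0.0611). Of 20 unfolded protein response genes 9 rose (9 adjusted over the list alone; median 0.84, adjusted p = 0.047 with an estimated correlation), among them Manf, a stress-induced secreted factor of the endoplasmic reticulum, at 1.30 ± 0.18. Of 29 NF-kB genes 11 rose (14 up and 1 down adjusted over the list alone; adjusted p = 0.047 with an estimated correlation), with 7 called without LPS replicate 2 or saline replicate 3. Of 14 MHC class II genes 6 fell (6 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), H2-Aa with a log2 fold change of -2.43 ± 0.37 and H2-Eb1 with -2.57 ± 0.39. This fall was not particular to MIA cortex. With LPS, 5 of these genes fell in control cortex, 3 in control striatum, where 1 rose, and 2 in MIA striatum. These counts also moved when 1 library was left out. In MIA cortex 4 of 22 MHC class I genes rose (7 adjusted over the list alone; adjusted p = 0.41 with an estimated correlation), and the count was 2 without saline replicate 2 or 3. Of 19 monocyte genes 5 rose (6 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation), and of 18 neutrophil genes 3 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.81 with an estimated correlation), with 1 fall without LPS replicate 2 or 3 or saline replicate 1.

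In MIA striatum, with 2 LPS libraries, LPS raised cytokine, phagocytic and blood leukocyte genes and raised few interferon genes. P2ry12 fell from 4568 ± 124 to 924 ± 127 CPM (-2.31 ± 0.21, adjusted p = 3.4e-07, n = 3 and 2), and Il1b rose from 110 ± 24.6 to 954 ± 46.6 CPM (3.12 ± 0.25, adjusted p = 7.8e-08). Ccl12 rose from 53.6 ± 5.49 to 261 ± 38.1 CPM (2.28 ± 0.30, adjusted p = 3.0e-05) and Fcgr4 from 21.4 ± 2.63 to 321 ± 12.2 CPM (3.91 ± 0.19). Isg15 was at 4.73 ± 0.465 CPM after LPS and 3.66 ± 0.49 CPM in saline (0.37 ± 0.55, adjusted p = 0.77), and Cxcl10 was at 1.17 ± 0.39 (adjusted p = 0.066). Tnf rose by 2.06 ± 0.28 and Cd14 by 1.82 ± 0.25. Tmem119 was at -0.49 ± 0.24 (adjusted p = 0.25), Cx3cr1 at -0.29 ± 0.16 (adjusted p = 0.31) and Tlr4 at 0.38 ± 0.28 (adjusted p = 0.49). The call was 1755 genes, 1188 higher and 567 lower, of which 646 and 339 changed at least 2-fold, and it was 945 without LPS replicate 1 and 758 without LPS replicate 2. With MIA cortex, 824 genes rose in both regions against 84 expected and 427 fell in both against 27 expected.

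Of 27 homeostatic genes 14 fell in MIA striatum (16 adjusted over the list alone; median -0.69, adjusted p = 0.0085 with an estimated correlation), and 9 did without LPS replicate 1. Of 28 cytokine genes 17 rose (20 adjusted over the list alone; median 1.49, adjusted p = 0.011 with an estimated correlation), and 11 did without LPS replicate 2. Of 27 phagocytic receptors 11 rose and 1 fell (14 and 3 adjusted over the list alone; adjusted p = 0.011 with an estimated correlation), Msr1 by 5.06 ± 0.32 and the formyl peptide receptor gene Fpr1 by 5.52 ± 0.60. The single fall was not called without LPS replicate 2, and 2 falls were called without saline replicate 3. Of 19 complement genes 8 rose (12 adjusted over the list alone; median 0.80, adjusted p = 0.022 with an estimated correlation), among them the factor B gene Cfb at 4.28 ± 0.57 and the anaphylatoxin receptor gene C5ar1 at 2.82 ± 0.39. Interferon genes rose in 8 of 40 cases (8 adjusted over the list alone; median 0.60, adjusted p = 0.56 with an estimated correlation). The interferon count was 5 without LPS replicate 1, 2 without LPS replicate 2, 5 without saline replicate 1 or 2 and 4 without saline replicate 3. Of 18 neutrophil genes 8 rose (12 adjusted over the list alone; median 3.87, adjusted p = 0.032 with an estimated correlation). Of 19 monocyte genes 12 rose (17 adjusted over the list alone; median 2.56, adjusted p = 0.011 with an estimated correlation). The monocyte count was 5 without LPS replicate 2 and 7 without saline replicate 2. The receptor gene Cxcr2 rose by 5.80 ± 0.69.

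**Figure D3:**
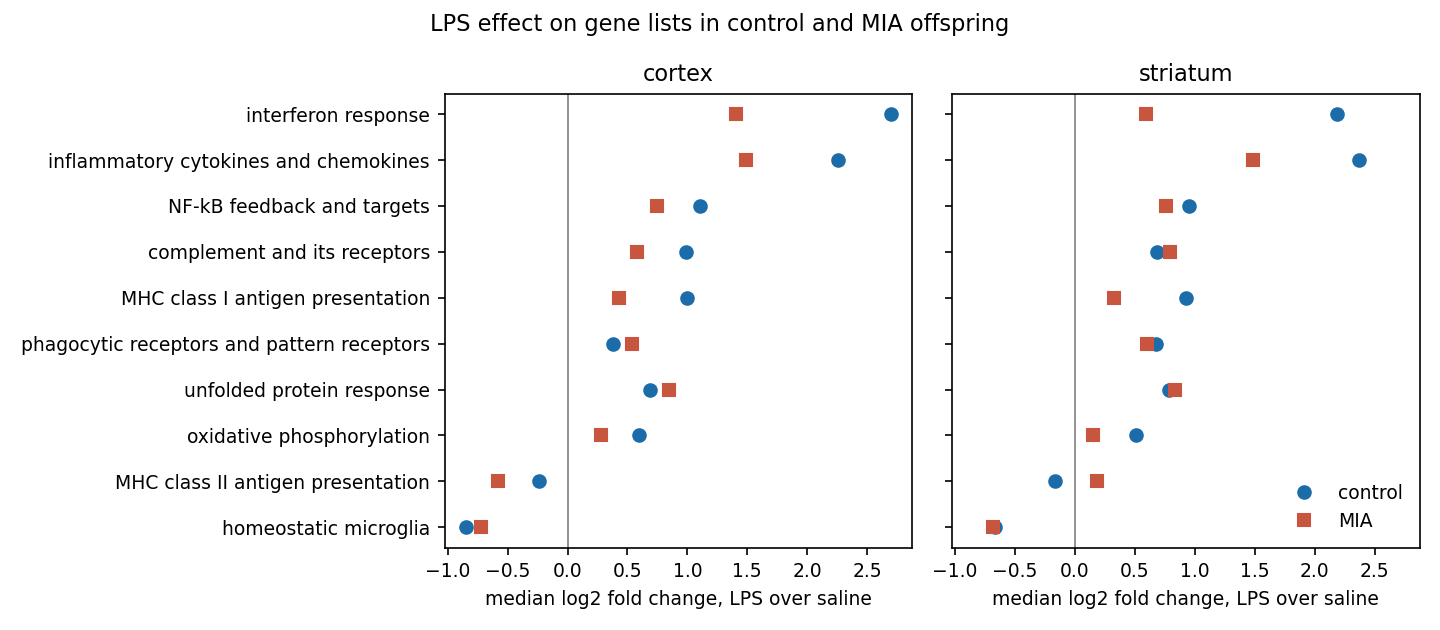
Median log2 fold change of LPS over saline (horizontal axes) for 10 gene lists (vertical axis) in cortex and striatum, with blue circles for control and red squares for MIA. The interferon medians are 2.70 and 2.19 in control and 1.41 and 0.60 in MIA cortex and striatum, while the homeostatic medians lie between -0.85 and -0.67.

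The size of the LPS response was compared between prenatal groups over genes called for the average LPS effect. The p-values by fry do not measure the spread between litters, which are not given. In cortex, 948 induced genes had a mean log2 fold change of 2.44 in control and 1.88 in MIA, a difference of -0.558 (adjusted p = 0.00015), and 77.7% of them rose less in MIA. The 748 repressed cortex genes had means of -1.95 and -1.82, a signed difference of -0.130 (adjusted p = 0.0313). In striatum, 912 induced genes had means of 2.29 and 2.09, a difference of -0.204 (adjusted p = 0.0561), and 826 repressed genes had means of -2.18 and -1.80, a difference of -0.375 (adjusted p = 0.0116). The induced-gene difference in cortex ran from -0.765 to -0.333 with each library left out in turn, with -0.361 and -0.333 without MIA saline replicates 2 and 3. The induced-gene difference in striatum passed by unadjusted fry p without control LPS replicate 2 (-0.295), control saline replicate 2 or 3 (-0.257 and -0.324) or MIA saline replicate 1 (-0.155). It was -0.104 and -0.350 without MIA LPS replicates 1 and 2, and -0.0969 and -0.0572 without MIA saline replicates 2 and 3. The repressed-gene difference in cortex was -0.377, -0.371 and -0.362 without control LPS replicates 1, 2 and 3, -0.218 without control saline replicate 1 and -0.205 without MIA saline replicate 2. It was 0.380 without MIA cortex LPS replicate 3, -0.0265 and -0.0293 without LPS replicates 1 and 2, and -0.0687 and -0.127 without saline replicates 1 and 3. The repressed-gene difference in striatum was -0.751, -0.656 and -0.590 without control LPS replicates 1, 2 and 3. It was 0.327 without MIA striatum LPS replicate 1, -0.0256 without LPS replicate 2 and -0.254 without saline replicate 3.

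In saline the question was whether microglia of MIA offspring differed from controls before any challenge. P2ry12 was at -0.21 ± 0.17 in cortex and -0.01 ± 0.17 in striatum (MIA minus control, log2, n = 3 and 3). Il1b was at 0.02 ± 0.22 and 0.16 ± 0.22, Tnf at 0.15 ± 0.25 and 0.15 ± 0.25. Isg15 was at 0.50 ± 0.51 and 0.35 ± 0.51. Tests with edgeR called 0 genes in cortex and 0 in striatum, with 921 and 842 genes at an unadjusted p under 0.05. limma voom called 0 and 242, and DESeq2 called 2 and 1. The edgeR count was 1 gene in cortex without MIA cortex saline replicate 3. Of the lists, the astrocyte median was 1.45 higher in MIA cortex (adjusted p = 0.27 with an estimated correlation), the neutrophil median 1.21 higher (adjusted p = 0.27 with an estimated correlation) and the endothelial median 0.89 higher (adjusted p = 0.27 with an estimated correlation), each a call with the preset correlation. MIA cortex saline replicate 1 stood apart in its group with a neutrophil score of 3.67 against 1.96 and 2.08. In striatum the median of the disease-associated microglia list was 0.29 higher in MIA (adjusted p = 0.085 with an estimated correlation), that of cytosolic ribosomal protein genes 0.52 higher (adjusted p = 0.50 with an estimated correlation), and that of endothelial genes was -0.72 (adjusted p = 0.46 with an estimated correlation).

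After LPS, some interferon genes were lower in MIA than in control striatum, but the list did not pass with an estimated correlation (adjusted p = 0.0548). A fit of these groups alone called 0 genes by edgeR (1556 at an unadjusted p under 0.05 in the shared fit, 95 by limma voom and 221 by DESeq2). Rtp4 (ENSMUSG00000033355.6), an interferon-induced chaperone of membrane receptors, was at 14.4 ± 3.36 CPM in MIA and 148 ± 30.5 CPM in control (log2 difference -3.36 ± 0.58, adjusted p = 0.025, n = 2 and 3). Ccl12 was at 261 ± 38.1 against 1074 ± 324 CPM (-2.04 ± 0.32, adjusted p = 0.017), and Irf9, part of the transcription factor complex of type I interferon signalling, at 68.3 ± 0.829 against 149 ± 16.1 CPM (-1.12 ± 0.19, adjusted p = 0.024). The asparagine synthetase gene Asns was at 11.5 ± 1.81 against 48.2 ± 14.3 CPM (-2.07 ± 0.39, adjusted p = 0.036), and the scavenger receptor gene Colec12 was higher, at 29.2 ± 3.03 against 9.71 ± 2.35 CPM (1.59 ± 0.29, adjusted p = 0.031). Il1b was at 0.36 ± 0.25 (adjusted p = 0.71) and Tnf at -0.33 ± 0.29 (adjusted p = 0.80). Ccl2 was at -1.41 ± 0.32 (adjusted p = 0.086), Cxcl10 at -1.39 ± 0.41 (adjusted p = 0.25), Isg15 at -2.09 ± 0.59 (adjusted p = 0.22) and P2ry12 at -0.13 ± 0.19 (adjusted p = 0.91). edgeR called 25 genes, 7 higher and 18 lower. The call was 1 without MIA striatum LPS replicate 1 or replicate 2, which ended the call of every gene named here, 15 without control striatum LPS replicate 1 and 90 without control striatum LPS replicate 3, and it was 1 with the excluded library added.

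Of the 40 interferon genes, 6 were called lower in MIA striatum after LPS and 36 were lower adjusted over the list alone, with a median of -1.65. They included Xaf1 at -2.44 ± 0.43 and Oasl2 at -2.63 ± 0.53. The called count was 3 without control LPS replicate 1, and 0 without either MIA LPS library, where 29 and 30 passed adjusted over the list alone. With the excluded library added it was 0 called and 25 adjusted over the list alone with a median of -1.31. Of 22 MHC class I genes 1 was called lower, Psme2 at 121 ± 13.4 against 218 ± 40.2 CPM (-0.85 ± 0.17, adjusted p = 0.046), and 15 were lower adjusted over the list alone (median -0.61, adjusted p = 0.20 with an estimated correlation). The MHC class I count adjusted over the list alone was 9 and 6 without control LPS replicates 1 and 3, and 2 and 4 without MIA LPS replicates 1 and 2. Of 16 border-associated macrophage genes 1, Colec12, was called higher, and 8 were higher adjusted over the list alone (median 0.96, adjusted p = 0.236 with an estimated correlation). Colec12 was not called without control LPS replicate 2 (adjusted p = 0.0765) or either MIA LPS library. The monocyte list, whose members rose with LPS in both prenatal groups, had a median difference of 0.28 between MIA and control LPS striatum (adjusted p = 0.91 with an estimated correlation).

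In cortex after LPS the interferon list was lower in MIA as a group, with no single gene called by edgeR in the fit of all 23 libraries. Rtp4 was at 59.7 ± 65.4 CPM in MIA and 195 ± 41.4 CPM in control, Ccl12 at 501 ± 279 against 1332 ± 136 CPM, and Isg15 at 11.5 ± 13 against 28.4 ± 7.12 CPM (-1.30 ± 0.49, adjusted p = 0.89, n = 3 and 3). Il1b was at 0.01 ± 0.22, Tnf at -0.43 ± 0.25, Ccl2 at -1.06 ± 0.27 (adjusted p = 0.30), Cxcl10 at -1.31 ± 0.36 (adjusted p = 0.38) and P2ry12 at 0.11 ± 0.17. The interferon median was -1.28, with 32 of 40 genes lower adjusted over the list alone (adjusted p = 0.0169 with an estimated correlation). That of MHC class I genes was -0.60, with 16 of 22 lower adjusted over the list alone (adjusted p = 0.0197 with an estimated correlation). That of disease-associated microglia genes was -0.21, with 1 of 24 lower adjusted over the list alone (adjusted p = 0.0207 with an estimated correlation). Single-gene tests with edgeR called 0 genes, 837 had an unadjusted p under 0.05, limma voom called 171 and DESeq2 called 57. The voom fit gave MIA cortex LPS replicate 3 a quality weight of 0.314, the lowest of the libraries used, against 1.21 and 2.45 for replicates 1 and 2. The voom count thus leaned little on that library. With a term for the replicate number, or with no low-count filter, edgeR also called genes, as given below.

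These counts moved with MIA cortex LPS replicate 3. Its interferon score of 6.22 lay among those of the control cortex LPS libraries (6.25, 6.18 and 6.63), while replicates 1 and 2 of its group lay at 4.25 and 4.19. Without replicate 3, edgeR called 89 genes in cortex, 7 higher and 82 lower, and 32 of the 40 interferon genes were called lower with a median of -2.12. In the same refit, chosen after the data were seen, 77 genes were lower in striatum, and 60 genes were lower in both regions against 0.37 expected from independent calls, which animals shared between regions would raise. Without control cortex LPS replicate 1 or 2, edgeR called 1 and 2 genes. The interferon count adjusted over the list alone was 14 without control LPS replicate 3, and 16 and 17 without MIA LPS replicates 1 and 2. For MHC class I genes it was 10 without control LPS replicate 3 or MIA LPS replicate 2.

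**Figure D4:**
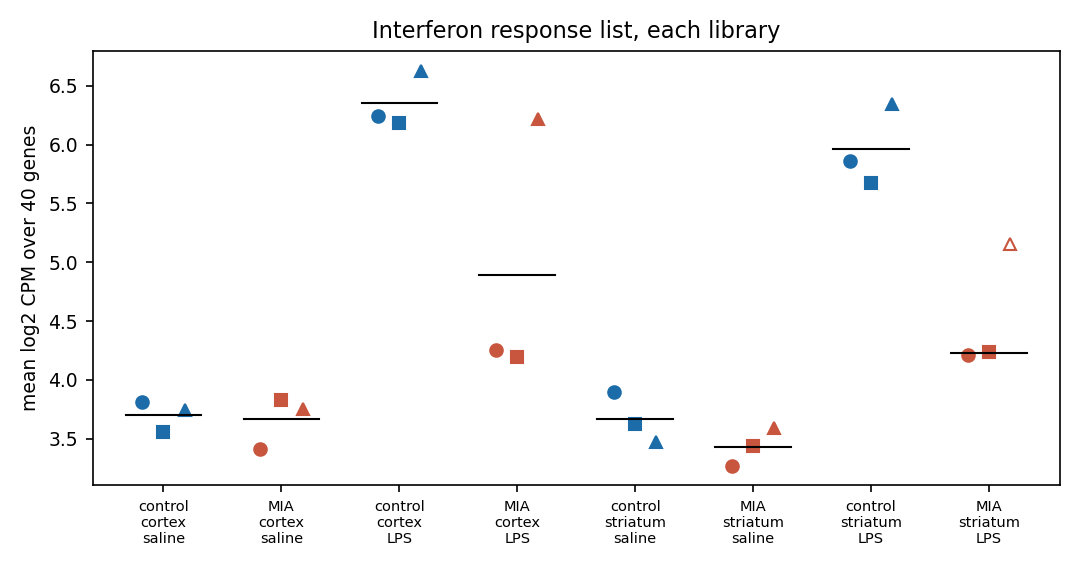
Mean log2 CPM over the 40 interferon response genes (vertical axis) for each library by group, with control in blue, MIA in red, circles, squares and triangles for replicates 1, 2 and 3, a hollow triangle for the excluded library and black bars for the mean of the libraries used. Control LPS libraries lie at 5.68 to 6.63, MIA LPS libraries at 4.19 to 4.25 except cortex replicate 3 at 6.22, and the excluded library at 5.16.

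Whether LPS acted differently in MIA and control was tested directly by the interaction. The interferon list had a median interaction of -1.50 in striatum, with 26 of 40 genes lower adjusted over the list alone (adjusted p = 0.162 with an estimated correlation), and of -1.11 in cortex, with 1 lower adjusted over the list alone (adjusted p = 0.101 with an estimated correlation). The median of the disease-associated microglia list was -0.36 in striatum, with 4 of 24 lower adjusted over the list alone (adjusted p = 0.11 with an estimated correlation). That of MHC class I genes was -0.86 with 8 of 22 (adjusted p = 0.16 with an estimated correlation). Tests of single genes with edgeR called 0 genes in cortex and 0 in striatum, with 744 and 1323 at an unadjusted p under 0.05. By limma voom the counts were 19 and 31, and by DESeq2 1 and 36. Without MIA cortex LPS replicate 3 edgeR called 35 genes in cortex, 1 higher and 34 lower, of which 18 were interferon genes, and 38 interferon genes passed adjusted over the list alone. It called 1 without MIA cortex saline replicate 3, and in striatum 1 without control LPS replicate 1 or 2. The striatal interferon count of 26 was 14 without control LPS replicate 3, 3 without MIA LPS replicate 1 and 17 without MIA LPS replicate 2.

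In saline, genes of striatal neurons, oligodendrocytes and vessels were among those higher in control striatum than in control cortex. The myelin gene Mbp was at 2010 ± 1410 CPM in striatum and 103 ± 21.8 CPM in cortex (4.28 ± 0.90, adjusted p = 0.038, n = 3 and 3). Penk was at 14.1 ± 6.55 against 0.919 ± 0.516 CPM (3.93 ± 0.64, adjusted p = 0.011) and the DARPP-32 gene Ppp1r1b at 31.5 ± 12.4 against 2.35 ± 0.788 CPM (3.74 ± 0.66, adjusted p = 0.019). The glucose transporter gene Slc2a1 was at 755 ± 180 against 273 ± 62.5 CPM (1.47 ± 0.29, adjusted p = 0.029). Ptger3, a prostaglandin E receptor gene, was lower in striatum, at 5.84 ± 0.75 against 19.7 ± 0.351 CPM (-1.75 ± 0.26, adjusted p = 0.0085). Emb was also lower, at 2.58 ± 0.0579 against 10.8 ± 3.86 CPM (-2.07 ± 0.32, adjusted p = 0.010). In all, 86 genes were called by edgeR, 78 higher and 8 lower in striatum.

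Of 19 striatal neuron genes 7 were higher in control striatum (18 adjusted over the list alone; median 3.73, adjusted p = 0.0087 with an estimated correlation). Of 23 endothelial genes 5 were higher (22 adjusted over the list alone; median 1.59, adjusted p = 0.055 with an estimated correlation). Of 20 oligodendrocyte genes 3 were higher (12 adjusted over the list alone; median 1.88, adjusted p = 0.095 with an estimated correlation), and 14 of 19 astrocyte genes were higher adjusted over the list alone (median 1.82, adjusted p = 0.22 with an estimated correlation). Of 16 border-associated macrophage genes 1, Cd209f, was lower (11 adjusted over the list alone; median -0.77, adjusted p = 0.062 with an estimated correlation), and of 27 phagocytic receptors 2 were lower (9 adjusted over the list alone; median -0.44, adjusted p = 0.055 with an estimated correlation). The total of 86 was 0 without cortex saline replicate 1, 4 without replicate 2 and 18 without replicate 3, and it was 8, 1 and 152 without striatum saline replicates 1, 2 and 3. The striatal neuron count of 7 was 0, 1 and 2 without cortex replicates 1, 2 and 3, and 3 and 0 without striatum replicates 1 and 2. The endothelial, oligodendrocyte and phagocytic counts were 0 without each of these 5 libraries, and the endothelial count was 9 without striatum replicate 3. The call of Cd209f ended without each of the 6 libraries.

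In MIA offspring in saline, neutrophil genes were lower in striatum than in cortex. S100a8, an abundant neutrophil gene, was at 9.73 ± 7.26 CPM in striatum and 121 ± 99.8 CPM in cortex (-3.64 ± 0.65, adjusted p = 0.034, n = 3 and 3), and the granule gene Ngp at 5.65 ± 5.81 against 93.5 ± 65.1 CPM (-4.04 ± 0.71, adjusted p = 0.034). Ptger3 was at 4.89 ± 0.453 against 17.9 ± 2.55 CPM (-1.87 ± 0.26, adjusted p = 0.0030) and Anxa1, which encodes the anti-inflammatory protein annexin A1, at 4.16 ± 1.47 against 22.4 ± 5.82 CPM (-2.42 ± 0.33, adjusted p = 0.0030). Retnla was higher in striatum, at 14.9 ± 9.77 against 1.08 ± 0.691 CPM (3.79 ± 0.68, adjusted p = 0.034). Of 18 neutrophil genes 4 were lower (14 adjusted over the list alone; median -3.54, adjusted p = 0.0014 with an estimated correlation). Of 19 monocyte genes 9 were lower adjusted over the list alone (median -1.01, adjusted p = 0.0023 with an estimated correlation), and 9 of 16 border-associated macrophage genes were lower adjusted over the list alone (median -0.89, adjusted p = 0.031 with an estimated correlation). Striatal neuron genes were higher in 14 of 19 cases adjusted over the list alone (median 2.69, adjusted p = 0.0036 with an estimated correlation). edgeR called 14 genes, 3 higher and 11 lower. The call was 5 and 8 without cortex replicates 1 and 2 and 4 without striatum replicate 1 or 2, and the neutrophil calls ended without cortex replicate 1 or striatum replicate 1 or 2. Cortex replicate 1 also held the most RNA of the hemoglobin gene Hbb-bs (chosen after its values were seen), at 338 CPM against 26.5 and 171.5 in replicates 2 and 3.

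The LPS effect was then compared between regions. In control the median of the endothelial list was -1.49 (striatum minus cortex), with 16 of 23 genes lower adjusted over the list alone (adjusted p = 0.39 with an estimated correlation), that of the astrocyte list -1.82 and that of the striatal neuron list -2.04 (each with adjusted p = 0.39 with an estimated correlation). The interferon median was -0.20 (adjusted p = 0.83 with an estimated correlation) and the cytokine median -0.04 (adjusted p = 0.94 with an estimated correlation). In MIA the neutrophil list rose more in striatum, with a median of 3.39 and 11 of 18 genes higher adjusted over the list alone (adjusted p = 0.009 with an estimated correlation), as did the monocyte list, with a median of 0.87 and 6 of 19 (adjusted p = 0.024 with an estimated correlation). No list was called by fry here (adjusted p = 0.056 and 0.078 for these lists). The neutrophil count of 11 was 4 without MIA striatum LPS replicate 2. The monocyte count of 6 was 0 without that library, 1 without cortex saline replicate 1 or striatum saline replicate 2, 2 without cortex LPS replicate 3 or striatum saline replicate 1, and 3 without cortex LPS replicate 1 or cortex saline replicate 2 or 3. The saline levels of both lists in MIA were lower in striatum than in cortex, and MIA cortex saline replicate 1 stood highest in its group for neutrophil genes. In single-gene tests edgeR called 0 genes in control and 0 in MIA, with 946 and 478 at an unadjusted p under 0.05. By limma voom the counts were 0 and 0 and by DESeq2 6 and 6. Without 1 library edgeR called 2 genes in control without control cortex LPS replicate 3 and 1 in MIA without MIA cortex saline replicate 3.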

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

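The tests of other-cell RNA, exchanged labels, numbering, response ratios, monocyte markers and regional carry-over in this part were chosen after the results were seen, for 3 patterns picked from 31 lists and 14 comparisons, and the rule that selected interaction lists for a closer look was chosen after the list values were seen.

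The LPS response of induced genes in cortex was smaller in MIA than in control, with all libraries and without any 1. The mean differences of repressed genes each reversed without 1 MIA LPS library. That of induced genes in striatum, -0.204, did not pass (adjusted p = 0.0561 by fry). The difference, MIA minus control, was -0.558 for induced genes and -0.130 for repressed genes in cortex and -0.375 for repressed genes in striatum. The induced cortex difference was -0.361 and -0.333 without MIA saline replicates 2 and 3. The repressed cortex difference was -0.377, -0.371 and -0.362 without control LPS replicates 1, 2 and 3, -0.218 without control saline replicate 1 and -0.205 without MIA saline replicate 2. It reversed to 0.380 without MIA cortex LPS replicate 3, was -0.0265 and -0.0293 without LPS replicates 1 and 2, and was -0.0687 and -0.127 without saline replicates 1 and 3. The repressed striatal difference was -0.751, -0.656 and -0.590 without control LPS replicates 1, 2 and 3. Its mean reversed to 0.327 without MIA striatum LPS replicate 1, where the median was -0.0411. It was -0.0256 without MIA striatum LPS replicate 2 and -0.254 without MIA striatum saline replicate 3. Among 100 of 200 splits of the cortex libraries, 1 gave a difference for induced genes as large as the real one, the real split itself. The highest other was 0.451. This share under 0.05 argues against chance only if the libraries are independent samples, which the labels do not settle, and it does not exclude chance. For repressed genes 41 of the 100 splits gave a difference as large, with 0.274 as the highest, so chance was not excluded. Residuals of MIA cortex LPS and saline libraries fitted best by number, a pattern picked from all pairs of groups. Among the 28 splits that keep these pairs together, a set chosen later, 1 and 13 gave differences as large for induced and repressed genes. The highest others were 0.380 and 0.229. The share was again under 0.05 for induced and not for repressed genes, with the same limit.

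Interferon genes had a median interaction of -1.50 between prenatal group and LPS in striatum, which passed with the preset correlation but not with an estimated one (adjusted p = 0.162). edgeR called 0 genes (1323 at an unadjusted p under 0.05, 31 by limma voom and 36 by DESeq2). The 26 interferon genes lower adjusted over the list alone were 14 without control LPS replicate 3, 3 without MIA LPS replicate 1 and 17 without MIA LPS replicate 2. In control LPS libraries every interferon score lay above those of the MIA LPS libraries except that of MIA cortex LPS replicate 3. A smaller response of all induced genes alike would lower cytokine genes as much. In striatum the median ratio of MIA to control LPS response was 0.780 over 24 cytokine genes (quartiles 0.489 and 0.979) and 0.354 over 33 interferon genes. Each gene was called for the average LPS effect of both prenatal groups. The ratios differed there, but their spread is over genes and not over libraries, with 2 MIA LPS libraries. The interferon list was also picked for its interaction, so these ratios do not decide the question. In cortex the medians were 0.706 and 0.571, with a lower cytokine quartile of 0.568, which does not separate them. NF-kB genes there, at 0.698, lay near the cytokine genes. Complement genes had 0.890 (quartiles 0.739 and 1.01) and MHC class I genes 0.436 (quartiles 0.344 and 0.525). The ratio thus differed between some lists in cortex too, with a spread over genes and not over libraries. Fewer blood monocytes in the MIA sorts would lower monocyte markers. Their median difference was -0.288 (SE 0.156 over 19 genes) in cortex and 0.278 (SE 0.207 over 19 genes) in striatum, where the markers showed no fall. These SEs leave out the spread between libraries, so a loss of monocytes is not excluded. A weaker interferon response of MIA microglia to LPS may underlie the pattern and remains a hypothesis, since differences between the animals, litters or handling of the 2 prenatal groups were not tested. Hbb-bs, a blood gene chosen after its values were seen, lay at 7.44 to 19.1 CPM in the MIA LPS libraries and at 29.6 to 125 CPM in the control LPS libraries, so a difference in blood content or handling stays open.

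The interferon score of MIA cortex LPS replicate 3 lay 1.99 above the mean of replicates 1 and 2. RNA of other brain cells, which this library held more of, predicted an excess of -0.362 (SE 0.495) from the slope within groups over 8 other LPS libraries, the excluded one left out. With that one added it predicted 0.493 (SE 0.560). Both lay below 1.99, but the SE covers the slope alone and not the scatter of 1 library. The marker score difference of 1.87 also lay beyond the differences within the other groups, so the test cannot decide. An exchange with a control LPS cortex library would leave a low control library, but the lowest control score lay 1.93 above the higher of replicates 1 and 2, which argues against an exchange within these groups as the cause of this pattern. With the cortex LPS libraries numbered 3 exchanged between prenatal groups, edgeR called 64 genes for MIA against control and 162 for the interaction, against 0 and 0 as labelled (837 and 744 at an unadjusted p under 0.05, 171 and 19 by limma voom, 57 and 1 by DESeq2), while the interferon median was -0.608 against -1.28. Why that exchange called more genes was not tested. Libraries numbered 3 also stood above numbers 1 and 2 by 0.415 in control cortex, 0.578 in control striatum and, for the excluded library, 0.931 in MIA striatum after LPS. The upper 95% prediction limit for 1 further group was 1.95, narrowly below 1.99, which by the rule used counts against a shared shift as the whole cause. This group was examined for its large excess, so that margin does not decide on a shift shared by libraries numbered 3. These libraries also scored lower for immediate early genes in 8 of 8 groups, the excluded library among them, a pattern picked after its values were seen that goes with some shared shift. The rule of this test was changed after its result was seen. The first rule, on controls alone, also counted against it, and another, with the margin added to the largest excess, left it open. Hbb-bs in this library, at 10.4 CPM, lay below the 69.3 to 125 CPM of control cortex LPS. The gene was chosen after the values of all libraries, this one included, were seen, so it cannot support the label. Its residuals fitted MIA cortex saline replicate 3 (r = 0.315) and MIA striatum LPS replicate 1 (r = 0.313) about as well. This library also resembled the excluded one in traits compared after the values were seen. Mitochondrial genes took 4.31% of its counts (3.26% and 2.75% in replicates 1 and 2) and 6.16% in the excluded library (2.49% and 2.37%). In the other groups number 3 had the lowest share, 1.93% to 2.72%. The other-cell marker score lay 1.87 and 1.17 above numbers 1 and 2 in these 2 libraries. Whether they share a cause was not tested. Left open are RNA of other brain cells, a shift shared by libraries numbered 3, and a real difference between animals. A single wrong label, with a library outside these groups, also remains open.

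Endothelial and pericyte genes had a median of -1.49 for the LPS effect in striatum minus cortex in control, which passed with the preset correlation but not with an estimated one (adjusted p = 0.39) or by fry (adjusted p = 0.41). edgeR called 0 genes (946 at an unadjusted p under 0.05, 0 by limma voom and 6 by DESeq2), and these genes stood high in control striatum saline. The 78 genes higher in control striatum than in cortex had a median rise of 1.96, and RNA of other cells carried into the sort was tested in 2 ways. With the other-cell marker score as covariate, the first test, the median rise was 1.32 (median SE 0.466 against 0.404 before) and 0 of the 78 genes were still called by edgeR. In the second test, over 70 of these genes and 17 libraries of the 6 other groups, 91.4% rose with the score against 47.0% of other genes, and the score difference predicted a rise of 0.615 (quartiles 0.365 and 0.874). The decision rule of this second test was changed after its result was seen. The rule first written would have counted 0.615 against carry-over as the whole cause, while the rule used leaves it open, so carry-over and regional expression cannot be told apart here. A lower share of microglia would raise all other cells alike, but endothelial genes lay 1.18 (SE 0.336 over list genes) above neuron genes in median rise. That SE leaves out the spread between libraries, so this explanation is not excluded.

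In MIA offspring the LPS effect on neutrophil genes was larger in striatum than in cortex by a median of 3.39 (adjusted p = 0.009 with an estimated correlation). The LPS effect on blood monocyte genes was also larger in striatum, by a median of 0.867 (adjusted p = 0.024 with an estimated correlation). By fry neither list passed (adjusted p = 0.056 and 0.078). MIA cortex saline replicate 1 had a neutrophil score of 3.67 against 1.96 and 2.08 in its group, and the most Hbb-bs RNA of the libraries used (338 CPM). Without it the neutrophil median was 2.69 and the 4 saline calls of lower neutrophil genes in striatum ended, as they did without MIA striatum saline replicate 1 or 2. The neutrophil median was 2.62 without MIA striatum LPS replicate 2.

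The MIA striatum LPS library left out of the comparisons had an interferon score of 5.16, above the saline libraries and above the 4.22 and 4.23 of the other 2 libraries of its group. It also had a striatal neuron score of 3.97, an astrocyte score of 6.23 and 6.16% of counts in mitochondrial genes.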

How the results depend on the processing

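With 2 or 3 libraries a group, the LPS effects in control cortex, control striatum and MIA cortex stayed within 1.5 times of the reported counts without any 1 library. The count for MIA in saline striatum stayed at 0 by edgeR (842 at an unadjusted p under 0.05, 242 by limma voom and 1 by DESeq2), and the other counts moved further. The size factors of the RLE method changed no count by more than 1.5 times. Over the named genes and the alternatives, 7224 calls were the same, 684 weaker and 31 stronger. Depth was 19453300 to 29480500 counts, and libraries of lower depth were not simulated. Where an alternative below used other libraries or genes its construction differs from the reported fit, and otherwise the cause was not tested.

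With no low-count filter, counts were 27 for MIA against control in LPS cortex, 81 in LPS striatum, 2 and 1 for the MIA by LPS interaction in cortex and striatum, 445 and 62 for region in control and MIA saline, and 7 for the LPS by region interaction in MIA. With replicate number as a block, which the labels do not give as animals, MIA against control gave 13 genes in LPS cortex and 42 in LPS striatum. With a block within prenatal group and treatment, region gave 627 genes in control and 78 in MIA saline, and the LPS by region interaction gave 2 in control. The block changed no other count by more than 1.5 times. With the compared groups fitted alone, LPS gave 2306 genes in control striatum and 1147 in MIA cortex, MIA against control in LPS striatum 0 by edgeR (1556 at an unadjusted p under 0.05 in the shared fit, 95 by limma voom and 221 by DESeq2), the MIA by LPS interaction in striatum 6, and region 533 in control and 2 in MIA saline. With the excluded library added, MIA against control in LPS striatum gave 1 gene and the repressed-gene response size in striatum was -0.446 and no longer passed.

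limma voom with quality weights called 3548 genes for LPS in MIA cortex and 3634 in MIA striatum, 242 for MIA in saline striatum, 171 and 95 for MIA in LPS cortex and striatum, 19 and 31 for the MIA by LPS interaction in cortex and striatum, and 1193 for region in control saline. MIA cortex LPS replicate 3 had the lowest weight, 0.314, so voom counts that involve its group come close to leaving it out. DESeq2 called 2 and 1 for MIA in saline cortex and striatum, 57 and 221 in LPS cortex and striatum, 1 and 36 for the MIA by LPS interaction, 586 and 95 for region in control and MIA saline, and 6 and 6 for the LPS by region interaction in control and MIA.

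With the other-cell marker score as covariate, added after the data were seen, counts were 36 and 111 for MIA in LPS cortex and striatum, 7 for the MIA by LPS interaction in striatum, 0 for region in control saline by edgeR (2030 at an unadjusted p under 0.05 without the covariate, 1193 by limma voom and 586 by DESeq2) and 1 for the LPS by region interaction in MIA. Response size was then -0.0445 for repressed cortex genes, which no longer passed, and -0.323 for induced striatal genes, which passed. With MIA cortex LPS replicate 3 left out of the shared fit, also added later, counts were 99 for MIA in LPS striatum, 23 for its interaction with LPS and 220 for region in control saline, and response size for induced striatal genes was -0.216 and passed.

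Response size over genes called in the other region was -0.127 for repressed cortex genes, which no longer passed, -0.185 for induced striatal genes, which passed, and -0.0228 for repressed striatal genes against -0.375 reported, which passed. With no minimum fold change it was -0.169 for induced striatal genes, -0.228 for repressed striatal genes and -0.288 for induced cortex genes, which passed. Over genes called in controls of the same region it was -0.522 for induced and -1.11 for repressed striatal genes and -0.602 for repressed cortex genes. Genes chosen by the control response favour a larger response there, so these values support nothing. Of 198 list calls 30 were kept with an estimated correlation, 80 by fry and 188 with the replicate block, and fry made 90 list calls in all.

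With each library left out in turn, counts ran from 0 to 89 for MIA in LPS cortex, 1 to 90 in LPS striatum and 0 to 1 in saline cortex, 0 to 35 and 0 to 1 for the MIA by LPS interaction in cortex and striatum, 0 to 152 and 4 to 13 for region in control and MIA saline, 0 to 2 and 0 to 1 for the LPS by region interaction in control and MIA, and 758 to 1468 for LPS in MIA striatum. These are edgeR counts, with voom and DESeq2 counts above. The libraries are named beside the results. Response size ran from -0.377 to 0.380 for repressed cortex genes, from -0.350 to -0.0572 for induced striatal genes and from -0.751 to 0.327 for repressed striatal genes. In MIA striatum a group left with 1 LPS library was assumed to vary like the other groups.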

Other observations

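Beyond the groups described above, some genes of complement and protein folding rose with LPS in control cortex, though neither list passed with an estimated correlation (adjusted p = 0.064 for both). Of 15 genes of cholesterol efflux and lipid storage 4 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with 2 falls called without control cortex LPS replicate 3 or saline replicate 3. Of these, Ch25h, which makes 25-hydroxycholesterol, rose from a mean of 1.07 to 20.4 CPM (4.25 ± 0.48, adjusted p = 3.0e-06, n = 3 and 3), and the lipid droplet gene Plin2 rose by 1.52 ± 0.23. Of 19 complement genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.064 with an estimated correlation), with Cfb at 6.55 ± 0.61 and C3ar1 at 0.99 ± 0.13. Of 20 unfolded protein response genes 8 rose (11 adjusted over the list alone; adjusted p = 0.064 with an estimated correlation), Manf by 1.31 ± 0.18 and Asns by 3.77 ± 0.37, and 5 were called without control cortex LPS replicate 1 or saline replicate 2. Of 23 glycolysis genes 8 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation), with the lactate dehydrogenase gene Ldha at 1.21 ± 0.11. Il7r, a cytokine receptor gene, fell from a mean of 53.9 to 9.37 CPM (-2.52 ± 0.23, adjusted p = 2.4e-07). The single fall among complement genes was not called without control cortex LPS replicates 1 or 2 or saline replicates 1 or 3.

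In MIA striatum genes of border-associated macrophages and of protein folding rose with LPS, in counts that rested on LPS replicate 2. The macrophage list did not pass with an estimated correlation. F13a1, a coagulation factor gene of macrophages, rose from 96.5 ± 29.1 to 432 ± 133 CPM (2.16 ± 0.44, adjusted p = 0.0023, n = 3 and 2), and was not called without LPS replicate 2 (adjusted p = 0.0695). Of 16 border-associated macrophage genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.24 with an estimated correlation), the sialoadhesin gene Siglec1 by 3.00 ± 0.44, and 1 rise was called without LPS replicate 2. The fall was not called without LPS replicate 1 or 2 or saline replicate 1 or 2. Of 20 unfolded protein response genes 9 rose (9 adjusted over the list alone; adjusted p = 0.022 with an estimated correlation), Manf by 1.40 ± 0.19, and 1 was called without LPS replicate 2.

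The genes in this paragraph were chosen after their values were seen. Hbb-bs, a hemoglobin gene, lay at 7.44 to 19.1 CPM in the MIA LPS libraries, at 17.8 to 338 CPM in the MIA saline libraries and at 29.6 to 125 CPM in the control libraries. The immediate early gene list was lowest in the library numbered 3 in 8 of 8 groups, the excluded library among them. It lay below the mean of numbers 1 and 2 by 0.581 log2 units on average (0.285 to 0.873).

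The reported counts were set beside those of other splits of the same libraries, a check planned beforehand. For LPS in control cortex, control striatum and MIA cortex, 1 of 10 splits, the real one, called as many genes as 3114, 3576 and 2039, and the highest other called 0 by edgeR. For region in control and MIA saline 1 of 10 splits called as many as 86 and 14, and the highest other called 1. For MIA in saline cortex and striatum 10 of 10 splits called as many as the real 0, with 0 as the highest other by edgeR (921 and 842 genes at an unadjusted p under 0.05, 0 and 242 by limma voom, 2 and 1 by DESeq2). For MIA in LPS cortex 10 of 10 did, with 64 as the highest other, the exchange of the libraries numbered 3 (837 at an unadjusted p under 0.05, 171 by limma voom and 57 by DESeq2), and for the interferon median of -1.28 there 1 of 10 did, with 1.13 in size as the highest other. A real count of 0 is reached by any split, and the 10 splits are too few for a share under 0.05.

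For the MIA by LPS interaction in cortex the real count by edgeR was 0, with 162 as the highest other (744 at an unadjusted p under 0.05, 19 by limma voom and 1 by DESeq2). For the LPS by region interaction in control it was 0, with 216 as the highest other (946 at an unadjusted p under 0.05, 0 by limma voom and 6 by DESeq2). Any split calls at least 0 genes, so 100 of 100 did in both and these splits decide nothing about chance. The split with 162 calls kept the saline libraries apart by prenatal group and exchanged the MIA and control LPS libraries numbered 3. The splits with 155, 177 and 216 calls kept the saline libraries apart by region and left 2 same-numbered pairs of LPS libraries together, as 5 of the 100 splits did. These splits point to a structure of the libraries, whose cause was not tested.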
